A study of Pseudoalteromonas sp. SCSIO_11900 with 3 samples.

How the data were processed

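RNA-seq was measured in wild-type Pseudoalteromonas sp. SCSIO_11900 in 3 states with 1 library each: planktonic cells, initial pellicle and mature pellicle. Per the labels' protocols, total RNA was isolated with a Tiangen RNAprep Pure kit and libraries were sequenced on an Illumina HiSeq instrument. The aligner, the read counter, the genome build and any treatment of strand, ribosomal RNA or reads that fit several places are not given in the sources used here. The labels do not say how many cultures each library came from.

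The authors' deposited table of the whole series lists 3106 genes by locus tag, with product, GO and KEGG text and a gene length. Per the file headers it gives a read count per gene, a coverage value and an RPKM value (reads scaled by gene length and library size) for each library. The deposited counts are whole numbers that sum to the totals in the file headers, 4558145 for planktonic cells, 3310468 for the initial pellicle and 1982008 for the mature pellicle. The deposited coverage is a ratio of covered length to gene length that reaches at most 1.0028. The deposited RPKM values equal the count divided by gene length and the library total, with a largest difference of 4.9e-06. Lengths were multiples of 3 for 99.9% of genes and so are coding lengths, from 156 to 4842 bp. A pair of deposited comparison tables, initial and mature pellicle against planktonic cells, hold the authors' log2 ratio, p-value and false discovery rate per gene. Checked against the RPKM values, the authors' deposited log2 is the ratio of RPKM with 0 set to 0.001, and 2 genes have no row in the initial pellicle table. The comparison tables also hold 8 columns of values per library, which were not used here.

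The choices below were made before the data were examined. Library sizes were scaled by TMM in edgeR 4.0.16 (R 4.3.3), with factors of 0.977 for planktonic cells, 0.886 for the initial pellicle and 1.16 for the mature pellicle. Genes with a mean of at least 20 reads over the 3 libraries were used, 2924 of 3106. The ratio of scaled counts of each gene was given with an exact 95% Clopper-Pearson interval of the conditional binomial share, and a gene was counted as higher or lower when its ratio was at least 2-fold and the interval left out 1. A library at 0 was set to 3 reads, which a count of 0 allows, and no ratio was given where both libraries held 3 reads or fewer. With 1 library per state there is no test across samples and no p-value was computed. No row is annotated as ribosomal or transfer RNA, so none was left out.

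Fixed gene lists were defined by patterns in the product text. Of 32 lists 26 had at least 5 measured members, and 3 had no member: prophage genes, type VI secretion, and ribosomal and transfer RNA. The median log2 ratio of a list was set against 10000 random lists of the same size matched on mean expression in 10 strata, and called apart below the 2.5th or above the 97.5th percentile, as a description of these libraries. Lists of fewer members were not set against random lists, and the text gives part of their members. A rule fixed which genes could be named for each comparison. It took the 8 highest and 8 lowest ratios of genes with a product and a mean of at least 100 reads. From the lists it took the 3 leading members of each list apart and up to 2 members of other lists. It also took all cellulose genes, curli genes with a ratio of at least 2-fold, and the 2 highest and 2 lowest hypothetical proteins. The text names part of the genes that this rule gave. The stretches of locus tags drawn in a figure, and the genes of the closing observations, were chosen after their values were seen.

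To show what counting noise in the shared planktonic library adds, 100 sets of unchanged libraries were drawn with Poisson noise, which leaves out variation between cultures. The intervals and calls were tested on simulated counts of 2924 genes with Poisson noise, scaled by the known library totals. These draws test neither TMM scaling nor variation between cultures. Of 50 genes changed 3-fold, 98% were recovered for the initial pellicle, 100% for the mature pellicle and 98% between the stages, and of 2724 unchanged genes 4, 2 and 4 were called. The interval held the true ratio for 95.5%, 96.0% and 95.8% of genes. Of 100 random lists 4, 5 and 6 were called apart. Those lists held genes drawn at random from simulated counts without links between genes. Fixed lists can hold neighbouring genes with correlated ratios, so these rates may not hold for them. Alternatives were DESeq2 1.42.0 size factors, total counts, upper-quartile factors, the deposited RPKM values plus 1, other count filters, a 4-fold threshold, an interval beyond 2-fold, and other ways to match or summarise lists. Thinning to equal depth, lists by product or KEGG text, and other scalings of the count of genes that went opposite ways were added after seeing the data. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.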

Results

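Pseudoalteromonas is a genus of marine bacteria, and a pellicle is a biofilm that cells build at the interface of liquid and air. RNA-seq of wild-type Pseudoalteromonas sp. SCSIO_11900 was measured in 3 states: planktonic (free-swimming) cells, an initial pellicle and a mature pellicle. Each state had 1 library. The planktonic library held about 4.6e+06 reads on 3106 genes, the initial pellicle library 3.3e+06 and the mature pellicle library 2.0e+06. The median gene had 262 reads in planktonic cells, 206 in the initial pellicle and 165 in the mature pellicle, and 3, 13 and 5 genes were listed at 0. A count of 0 allows up to 0.673, 1.02 and 1.31 counts per 1e+06 scaled reads in the planktonic, initial and mature libraries. Because each state had 1 library, no difference has a replicate check, no test across samples was made, and all intervals are 95% intervals that cover counting error only. Genes are named by the product text and locus tag of the deposited table, without coordinates. The 3 comparisons ask how transcript levels of each pellicle stage differ from planktonic cells, and how the stages differ from each other.

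The initial pellicle library had far more reads of curli genes and of the protease gene next to them than the planktonic library. Curlin (BG00_RS15370), the subunit of the curli amyloid fibre, was 155-fold higher (interval 137 to 175). The curli assembly proteins CsgE (BG00_RS15365) and CsgF (BG00_RS15360) were 20.5-fold (12.3 to 36.5) and 20.1-fold (13.1 to 32.2) higher, and 3 of the 4 measured members of the curli, amyloid and adhesin list were at least 2-fold higher. Peptidase S8 (BG00_RS15375), a subtilisin-type serine protease with the next locus tag after curlin, was 450.4-fold higher (385 to 530.2), the largest ratio among genes with a mean of at least 100 reads and a named product. The list of extracellular peptidases and proteases went both ways, with 6 of 25 members higher, 3 lower and a median log2 ratio of 0.15 within its random range. A LuxR-family regulator with a nearby locus tag (BG00_RS15350) was 3.91-fold higher (3.28 to 4.68).

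Breakdown of fatty acids and amino acids had the highest median of the 26 lists tested in the initial pellicle. Of its 26 measured members 22 were at least 2-fold higher, 1 was lower and 3 lay between, and its median log2 ratio of 3.31 lay above the range of matched random lists (-0.38 to 0.61). Acyl-CoA dehydrogenase (BG00_RS11480) was 277-fold higher (183 to 443), methylmalonate-semialdehyde dehydrogenase (BG00_RS11485), an enzyme of valine breakdown, 162-fold (123 to 217) and enoyl-CoA hydratase (BG00_RS11475) 101-fold (74.7 to 141). These 3 genes lie in a run of 15 consecutive locus tags (BG00_RS11460 to BG00_RS11530), all at least 4-fold higher. Their ratios need not be independent, and how many list members lie in that run was not counted. An aldehyde dehydrogenase (BG00_RS15450) outside the breakdown list was 264-fold higher (205 to 348). A long-chain fatty acid transporter (BG00_RS00960), also outside it, was 12.2-fold lower (10.98 to 13.6). In the tricarboxylic acid cycle and glyoxylate list, 11 of 27 members were higher and 2 lower, and its median of 0.26 lay within the random range. Its largest ratios were those of aconitate hydratase (BG00_RS04965), 48.3-fold higher (44.2 to 52.7), and of isocitrate lyase (BG00_RS14630), which opens the glyoxylate shunt, 40.3-fold higher (34.5 to 47.5). Among the 11 are methylcitrate genes of propionate use that its name pattern caught. These are BG00_RS12435, BG00_RS12440 and BG00_RS12445, which were 18.2-fold, 33.0-fold and 20.5-fold higher.

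Several outer membrane receptors and haem uptake genes were also higher in the initial pellicle. A ligand-gated channel protein (BG00_RS15765), whose KEGG text names an iron complex receptor, was 259-fold higher (189 to 364), and a TonB-dependent receptor (BG00_RS07425) 123-fold higher (107 to 143). A membrane protein whose KEGG text names a haemoglobin, transferrin or lactoferrin receptor (BG00_RS14465) was 201-fold higher (163 to 251), and the hemin transporter substrate-binding protein (BG00_RS14460) 78.3-fold (59.2 to 106). BG00_RS15765 and BG00_RS14465 are in neither of the fixed lists for receptors and iron, which went both ways. Of 19 TonB-dependent receptors 8 were higher and 3 lower, with BG00_RS12745 24.7-fold lower (22.7 to 26.8) and BG00_RS15275 13.1-fold lower (10.3 to 16.8). Of 17 iron uptake and storage genes 5 were higher and 1 lower. Neither list's median, 0.58 for the receptors and 0.09 for the iron genes (-0.05 with total counts), left its random range.

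Pilus genes had a median log2 ratio of 0.94 in the initial pellicle, with 7 of 16 members higher and none lower, and a fimbrial protein (BG00_RS02040) was 11.3-fold higher (11 to 11.6). Type II secretion, which exports folded proteins across the outer membrane, had 7 of 15 members higher and none lower, with a median of 1.0. GspF (BG00_RS02975) of that system was 2.75-fold higher (2.40 to 3.17). Amino acid biosynthesis had 16 of 49 members higher and 3 lower with a median of 0.49, and oxidative stress defence 10 of 33 higher and 2 lower with a median of 0.41, led by a glutathione S-transferase (BG00_RS14970) at 12.9-fold (10.4 to 16.2). The flagellum and motor list had a median of 0.37, with 9 of 43 higher, among them flagellin (BG00_RS07850) at 3.19-fold (2.81 to 3.63) and the filament cap protein FliD (BG00_RS07855) at 3.04-fold (2.81 to 3.30). Its largest ratio belonged to a gene with the product text MotA (BG00_RS05865), 5.90-fold higher (5.43 to 6.41), whose KEGG text names ExbB, an energiser of outer membrane transport, instead. All 5 medians lay above their random ranges.

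Genes lower in the initial pellicle included a respiratory oxidase and sulfate assimilation. Cytochrome o ubiquinol oxidase subunit I (BG00_RS00075), of a terminal oxidase that reduces oxygen, was 36.0-fold lower (24.1 to 56.4) and its neighbour by locus tag (BG00_RS00080) 32.3-fold lower (18.4 to 62.9). Of 11 sulfate assimilation and cysteine synthesis genes 6 were lower and none higher, with a median log2 ratio of -1.73. Phosphoadenosine phosphosulfate reductase (BG00_RS04950) was 13.8-fold lower (8.60 to 23.5), the alpha subunit of sulfite reductase (BG00_RS04940) 13.2-fold (10.3 to 17.1) and siroheme synthase (BG00_RS05220), which makes the cofactor of sulfite reductase, 19.0-fold (10.5 to 38.5). Ribosomal proteins had a median of -0.66, with 10 of 52 members at least 2-fold lower and none higher. Translation factors and tRNA synthetases had a median of -0.64, with 4 of 40 lower and 1 higher. Elongation factor G (BG00_RS05295), which moves the ribosome along the mRNA, was 2.60-fold lower (2.56 to 2.63). The largest negative ratio in the translation list was that of GreB (BG00_RS03285), a transcription factor that its name pattern caught. Transposases had a median of -1.07, with 6 of 9 lower and 2 higher, and whether reads were shared between similar copies was not tested.

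Chaperones and heat-shock proteases had 7 of 17 members higher and 2 lower, with a median of 0.47 within the random range, and the co-chaperonin GroES (BG00_RS02695) was 16.4-fold higher (15.0 to 18). Respiratory chain genes went both ways, with 9 of 23 higher and 5 lower. In chemotaxis, 4 of 38 members were higher and 2 lower, with a chemotaxis protein (BG00_RS02165) 10.9-fold lower (8.87 to 13.6). The hypothetical proteins BG00_RS00965 and BG00_RS03825 were 68.2-fold (32.7 to 171) and 62.4-fold (54.2 to 72.1) higher. The hypothetical proteins BG00_RS13260 and BG00_RS03295 were 18.2-fold (17.2 to 19.4) and 15.8-fold (9.60 to 27.9) lower.

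In all, 541 of 2924 genes were at least 2-fold higher and 291 at least 2-fold lower in the initial pellicle library than in the planktonic library. The split depended on scaling: with total counts 470 genes were higher and 398 lower, with the deposited RPKM values 464 and 383, and with upper-quartile factors 416 and 528. The median log2 ratio of all genes was -0.02 with TMM, -0.16 with total counts and -0.30 with upper-quartile factors. The places of the flagellum, oxidative stress, transposase, type II secretion and amino acid biosynthesis lists outside random lists were lost when the mean replaced the median, that of oxidative stress also with length-matched lists or a mean of at least 100 reads, and the transposase median was 0.27 when KEGG text was added.

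**Figure D1:**
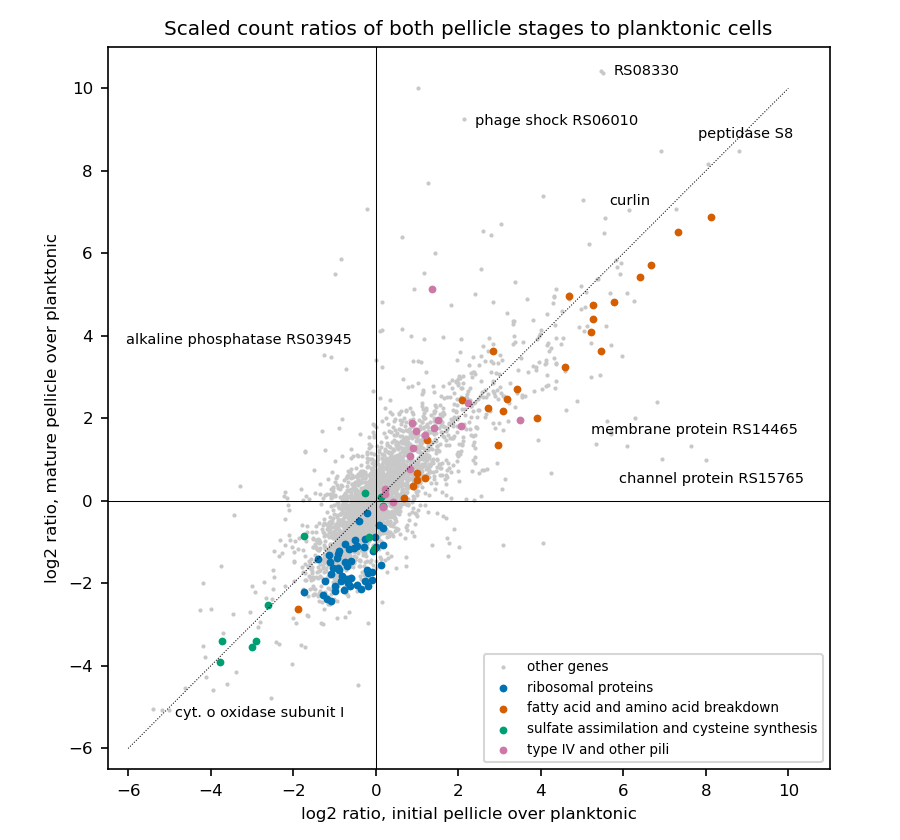
Each point is 1 of 2924 genes, with the log2 ratio of initial pellicle over planktonic cells on the horizontal axis and of mature pellicle over planktonic cells on the vertical axis, 4 gene lists in colour and equal ratios on the dotted line. Most breakdown genes lie to the upper right with curlin and peptidase S8, most ribosomal proteins lie below the line, and the haem uptake receptor BG00_RS14465 lies far to the right near the axis.

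Curli genes and peptidase S8 (BG00_RS15375) were also far higher in the mature pellicle than in the planktonic library. Curlin was 134-fold (119 to 152) and peptidase S8 357-fold (305 to 420.3) higher than in planktonic cells, CsgE 34.9-fold (21.1 to 61.9) and CsgF 31.0-fold (20.4 to 49.6). Of the 25 extracellular peptidases and proteases 6 were higher and 3 lower, with a median log2 ratio of 0.11 within the random range. Breakdown genes were higher in 20 of 26 cases and lower in 1, with a median log2 ratio of 2.59. Acyl-CoA dehydrogenase (BG00_RS11480) was 118-fold higher (77.3 to 188). It lies in a run of 13 consecutive locus tags (BG00_RS11460 to BG00_RS11520), all at least 4-fold higher. The long-chain fatty acid transporter BG00_RS00960, outside the list, was 21.5-fold lower (18.4 to 25.3). The aldehyde dehydrogenase BG00_RS15450 was 288-fold higher (223 to 378).

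A pair of hypothetical proteins, BG00_RS08330 and BG00_RS08335, were 1368-fold (1043 to 1832) and 1321-fold (1042 to 1702) higher than in planktonic cells, and a fimbrial assembly protein nearby by locus tag (BG00_RS08350), whose KEGG text names an outer membrane usher, was 35.1-fold higher (26.5 to 47.5). A phage shock protein (BG00_RS06010), of a family that responds to inner membrane stress, was 614-fold higher (343 to 1230.4), from 11 planktonic reads. A membrane protein close to it by locus tag (BG00_RS06020) was 135-fold higher (65.1 to 338), from 7 planktonic reads. A cold-shock protein (BG00_RS12340) was 357-fold (226 to 603) and ribosome modulation factor (BG00_RS11285), which pairs idle ribosomes in stationary phase, 156-fold higher (60.4 to 576), the latter from 4 planktonic reads. The list of cold shock and stationary phase genes went both ways, with 5 of 11 higher, 4 lower and a median of 0.42, within the random range.

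Pilus genes were higher in 11 of 16 cases and lower in none, with a median log2 ratio of 1.64 against a random range of -0.55 to 0.75. Genes that make, break down or bind cyclic di-GMP, a second messenger of biofilm formation, had 13 of 33 members higher and 4 lower with a median of 0.74. Diguanylate cyclase BG00_RS08190 was 15.5-fold (12.2 to 19.96) and diguanylate cyclase BG00_RS09955 5.77-fold higher (5.20 to 6.41), while a phosphodiesterase, which degrades the messenger (BG00_RS10005), was 5.73-fold higher (4.61 to 7.17). Type II secretion had 8 of 15 members higher with a median of 1.27, led by GspB (BG00_RS00245) at 4.18-fold (3.46 to 5.08), and amino acid biosynthesis 14 of 49 higher and 1 lower with a median of 0.57, led by 3-phosphoshikimate 1-carboxyvinyltransferase (BG00_RS12490) at 7.76-fold (6.26 to 9.70). These 4 medians lay above their random ranges. The capsule and exopolysaccharide list, with 6 of 13 higher, had a median of 0.68 within its random range.

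Ribosomal proteins had the lowest median of the 26 lists tested in the mature pellicle. Of 52 ribosomal proteins 45 were at least 2-fold lower and none higher, with a median log2 ratio of -1.63 against a random range of -0.88 to -0.07. Ribosomal proteins took 22.1% of all reads in planktonic cells, 13.6% in the initial and 8.96% in the mature pellicle. Ribosomal protein L16 (BG00_RS04925) was 5.38-fold lower (5.18 to 5.6), S3 (BG00_RS04920) 5.17-fold (4.97 to 5.39) and elongation factor G 5.36-fold (5.25 to 5.48). Translation factors and tRNA synthetases had 18 of 40 members lower and 1 higher with a median of -0.94. Both genes for elongation factor Tu (BG00_RS05300 and BG00_RS03575), which delivers aminoacyl-tRNA, were lower by 5.41-fold (5.23 to 5.6) and 4.93-fold (4.78 to 5.09), though reads may be split between these copies. Sulfate assimilation again had 6 of 11 members lower and none higher, with a median of -1.16, and phosphoadenosine phosphosulfate reductase was 14.9-fold lower (8.61 to 28.3). The cytochrome o oxidase subunit I gene was 33.7-fold lower (21.7 to 55.4), and S-adenosylmethionine synthetase (BG00_RS07310), which makes the main methyl donor, 15.6-fold lower (13.8 to 17.5). TonB-dependent receptors went both ways, with 7 of 19 higher and 5 lower and a median of 0.13 within the random range. Their log2 ratios ran from -4.55 for BG00_RS12745 to 5.85 for BG00_RS08140.

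In all, 652 of 2924 genes were at least 2-fold higher and 441 lower in the mature pellicle library than in the planktonic library. With total counts 799 were higher and 305 lower, with the deposited RPKM values 786 and 301, and with upper-quartile factors 550 and 617, and the median log2 ratio of all genes was 0.06 with TMM, 0.30 with total counts and -0.16 with upper-quartile factors. The places of the cyclic di-GMP and amino acid biosynthesis lists were lost when the mean replaced the median.

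**Figure D2:**
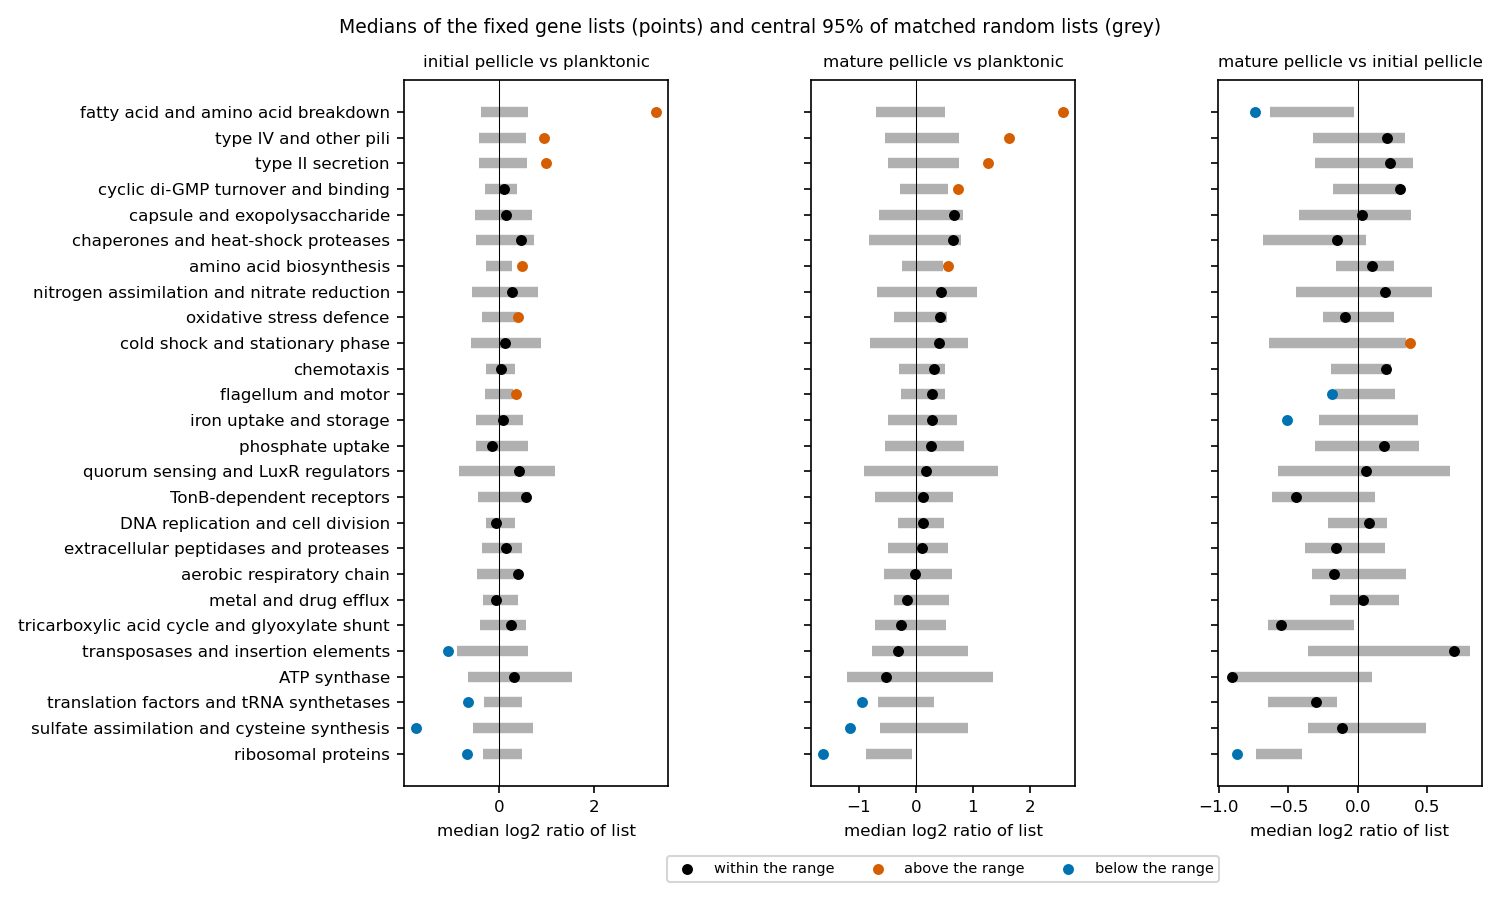
Points are the median log2 ratios of the 26 fixed gene lists with at least 5 measured members in each of the 3 comparisons, and grey bars span the central 95% of 10000 random lists matched on expression. Breakdown genes lie above the bars in both comparisons with planktonic cells (3.31 and 2.59) and ribosomal proteins lie below them in all 3 comparisons (-0.66, -1.63 and -0.87).

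Between the pellicle stages, several haem uptake and receptor genes were far lower in the mature pellicle. The channel protein BG00_RS15765 was 129.7-fold lower (95.2 to 182) in the mature than in the initial pellicle, the haemoglobin-type receptor BG00_RS14465 80.0-fold (66.4 to 97.3), the TonB-dependent receptor BG00_RS07425 60.9-fold (52.9 to 70.4) and the hemin transporter substrate-binding protein BG00_RS14460 19.5-fold lower (16 to 24.0). Iron uptake and storage genes had 5 of 17 members lower and 2 higher, with a median log2 ratio of -0.51 below the random range. Of 19 TonB-dependent receptors 4 were lower, 1 was higher and 14 lay between, and their median of -0.45 lay within the random range. A gene with the product text molybdenum ABC transporter permease (BG00_RS05875), whose KEGG text names a catecholate siderophore receptor instead, was 17.8-fold lower (16.9 to 18.7). Isocitrate lyase was 15.6-fold lower (13.6 to 18) and a cellulose-binding protein (BG00_RS03865) 11.9-fold lower (9.98 to 14.2). The latter was 19.0-fold higher in the initial pellicle than in planktonic cells (16.2 to 22.4). The other member of the cellulose list (BG00_RS00445), also a cellulose-binding protein, had small ratios. Its log2 ratios were -0.68 in the initial and -0.32 in the mature pellicle against planktonic cells, and 0.36 between the stages.

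Ribosomal proteins were lower again in the mature than in the initial pellicle, with 25 of 52 members at least 2-fold lower and none higher. Their median of -0.87 lay below a random range of -0.73 to -0.40. That range was itself negative, but random lists could also draw ribosomal proteins. It therefore does not show how other genes of like expression behaved on their own. L7/L12 (BG00_RS05270) was 3.65-fold lower (3.54 to 3.76). Translation factors and tRNA synthetases, with 4 of 40 members lower and 2 higher, had a median of -0.30 within the random range. Breakdown genes had 6 of 26 members lower and none higher with a median of -0.74, led by urocanate hydratase (BG00_RS05490) of histidine breakdown at 3.78-fold lower (3.36 to 4.27). The flagellum and motor list had 1 member higher and 1 lower of 43 and a median of -0.18 with TMM, which was 0.20 with total counts.

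Among the genes with the largest ratios of mature over initial pellicle were phage shock proteins and a lipoprotein (BG00_RS03925), 103-fold higher (63.9 to 177). The phage shock proteins BG00_RS06010, BG00_RS08640 and BG00_RS08650 were 139-fold (98.1 to 203), 54.5-fold (49.1 to 60.6) and 20.7-fold (17.4 to 24.6) higher than in the initial pellicle. The other genes with that product, looked up after their values were seen, had log2 ratios of 6.48 (4.60 to 9.54) for BG00_RS06015, 3.05 (2.75 to 3.36) for BG00_RS08645, 0.90 (0.80 to 0.99) for BG00_RS04345 and 0.50 (0.10 to 0.90) for BG00_RS12865, the last pair under 2-fold. The ratio of BG00_RS06015 rests on 2 reads in the initial pellicle. The hypothetical protein BG00_RS16520 was 506-fold higher (197 to 1858), from 4 reads in the initial pellicle and 1580 in the mature pellicle. Alkaline phosphatase, which frees phosphate from organic compounds, was 28.0-fold higher (17.3 to 48.6) for BG00_RS03945 and 10.6-fold (7.69 to 14.9) for BG00_RS03940. These genes belong to the phosphate uptake list, in which 3 of 12 members were higher and 9 lay between. All 3 were alkaline phosphatases, the other being BG00_RS06875 with 41 reads in the initial and 130 in the mature pellicle library. The list's median of 0.18 lay within its random range. The cold shock and stationary phase list had 2 of 11 members higher and none lower, with a median of 0.38 above its random range. Ribosome modulation factor was 4.83-fold higher (3.80 to 6.21).

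In all, 234 genes were at least 2-fold higher and 238 lower in the mature than in the initial pellicle library. With total counts 514 were higher and 109 lower, and with the deposited RPKM values 497 and 109, and the median log2 ratio of all genes was 0.01 with TMM and 0.39 with total counts, so the balance of higher and lower genes rests on the scaling. The places of the flagellum, breakdown and cold shock lists were lost when the mean replaced the median, those of the flagellum and cold shock lists also without matching on expression, that of the flagellum list with a mean of at least 100 reads, and that of the iron list without a filter on low counts.

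**Figure D3:**
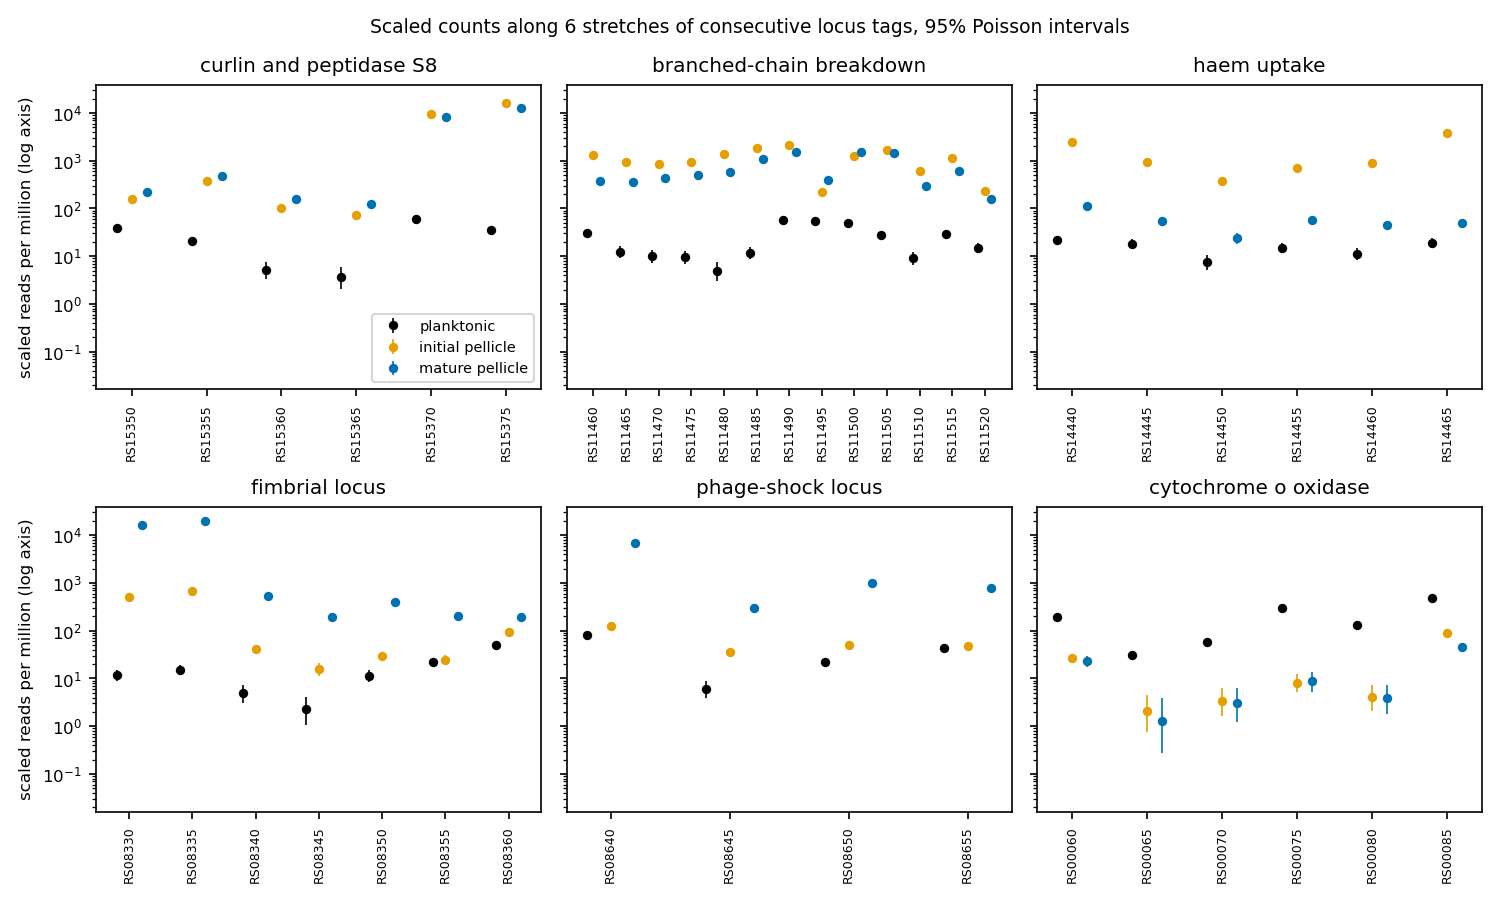
Counts per 1e+06 scaled reads on a log axis for genes along 6 stretches of consecutive locus tags, with 1 point per library and 95% Poisson intervals that cover counting error only. Curlin was 155-fold and 134-fold higher in the initial and mature pellicle than in planktonic cells, the haem receptor gene BG00_RS14465 201-fold and 2.51-fold, the hypothetical protein BG00_RS08330 of the fimbrial stretch 43.9-fold and 1368-fold, and cytochrome o oxidase subunit I was 36.0-fold and 33.7-fold lower.

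Both pellicle stages were compared with the same planktonic library. At least 2-fold higher in both were 426 genes, where independent lists would share 121 and simulated unchanged libraries shared 0.29 on average. At least 2-fold lower in both were 190 genes, against 43.9 and 0.23. Across genes, which are not independent replicates, the log2 ratios had a Pearson correlation of 0.80 and a covariance of 1.75, against 0.35 and 0.0168 in the simulations. The simulations hold counting noise only and no variation between cultures, and part of the excess may come from the shared planktonic library.

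The authors' deposited tables give a log2 ratio and a false discovery rate for each pellicle stage against planktonic cells. At least 2-fold and a rate of at most 0.05, the authors' deposited table for the initial pellicle holds 493 higher and 420 lower genes of 3104, of which 470 and 291 were also called here in the same direction. The authors' deposited table for the mature pellicle holds 853 higher and 310 lower genes of 3106, of which 652 and 305 were also called here. The ratios in the authors' deposited tables are those of RPKM values, so the TMM-scaled ratios minus those ratios give a constant on the log2 scale, 0.14 for the initial and -0.24 for the mature pellicle. The test behind those rates is not given in the sources used here, and with 1 library per state it compares libraries, not conditions.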

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

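The genes of the next paragraph were picked out because both pellicle stages were compared with planktonic cells and went opposite ways. These differences were not tested, since each state had 1 library. The haem uptake stretch and the ribosomal protein list further below were not picked for that reason. The tests of scaling for the genes that went opposite ways, of depth, of neighbouring genes, of iron acquisition genes and of near-identical copies were chosen only after values behind them had been seen. The iron test was made stricter after its result was known.

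At least 2-fold higher in the initial pellicle and at least 2-fold lower in the mature pellicle than in planktonic cells were 6 genes, and 6 genes went the other way. The log2 ratio of mature over initial pellicle was -5.07 for the TonB-dependent receptor BG00_RS04220, -4.15 for BG00_RS05875, whose KEGG text names a siderophore receptor, and -3.13 for the hypothetical protein BG00_RS03910. It was 4.81 for alkaline phosphatase BG00_RS03945, 4.57 for the lipoprotein BG00_RS01790 and 2.93 for cystathionine gamma-synthase BG00_RS05575, which acts in methionine synthesis. These counts rest on the scaling: with total counts 1 gene was higher in the initial and lower in the mature pellicle and 8 went the other way, with upper-quartile factors 7 and 8, and with DESeq2 factors 6 and 6. Mature pellicle ratios over planktonic cells such as -1.01 for BG00_RS04220, -1.06 for BG00_RS05875 and -1.12 for BG00_RS03910 lie near the 2-fold threshold.

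The 6 genes of the haem uptake stretch of consecutive locus tags (BG00_RS14440 to BG00_RS14465) had log2 ratios from 5.6 to 7.65 in the initial pellicle and from 1.33 to 2.40 in the mature pellicle against planktonic cells. Reads of near-identical copies stay open, because the covered length, a median ratio of 0.999 in the initial pellicle library, was already 0.976 in planktonic cells and could not have fallen. A wider response of iron acquisition genes stays open, since the median of 41 other genes with iron complex, siderophore, ExbB, ExbD or TonB in their KEGG text lay at percentile 99.8 of random lists, but at 96.1 without 4 of them with high ratios seen before, and the fixed iron list was not apart in this comparison. That removal can only lower the median, the 37 left still hold genes named for their ratios, such as BG00_RS12745, and the 15 of them that are not receptors lay at 69.2. The pellicle stage and variation between cultures were not tested as explanations.

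Ribosomal proteins were lower in the mature pellicle than in planktonic cells (median log2 ratio -1.63). Gene length bias is argued against by random lists matched on coding length as well as expression, where the median lay at percentile 0. Lower depth of the mature pellicle library adds counting error, which the counting intervals cover. They lay wholly below a ratio of 1 for 52 of 52 members. Ribosomal proteins took 22.1% of reads in planktonic cells and 8.96% in the mature pellicle, shares that are relative to each library's total. These values argue against counting error from lower depth for this list. They are not a separate test, since 45 members had been called lower from the same intervals. The pellicle stage and variation between cultures stay open, and were not tested.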

How the results depend on the processing

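Tests with lists by product or KEGG text and with thinned libraries were chosen after seeing the data. No paired analysis was possible because each state has 1 library and no test was made, and keeping ribosomal and transfer RNA was not run because no row is annotated as such. DESeq2 size factors left every count of higher and lower genes within 1.5 times, as did thinning to equal depth and no filter on low counts. Between the stages, total counts gave 514 higher and 109 lower genes and RPKM values 497 and 109, and a mean count of at least 100 gave 127 higher. Against planktonic cells, 528 genes were lower in the initial pellicle with upper-quartile factors and 190 with a mean count of at least 100. The 4-fold threshold gave 256 higher and 54 lower genes for the initial pellicle, 293 and 96 for the mature pellicle, 57 and 41 between the stages, and 197 and 33 shared, fewer by construction, and the authors' deposited tables held 240 higher and 77 lower genes for the initial and 401 and 68 for the mature pellicle at that threshold. An interval beyond 2-fold left 149 lower genes in the initial pellicle, 293 lower in the mature pellicle, and 110 higher and 152 lower between the stages, also by construction. Random lists without matching set 9 lists apart between the stages in place of 5, and product or KEGG text 13 in place of 8 in the mature pellicle. The flagellum list between the stages had a median of 0.20 with total counts, which shift all genes alike, and the transposase list in the initial pellicle one of 0.27 with KEGG text, which gave it 13 members in place of 9; the cause was not tested further. Of 23 list medians apart, counted over all comparisons so that a list can count more than once, the mean in place of the median kept 13. Matching on length kept 22. For genes named by rule, 226 of 236 ratios stayed inside their counting interval with DESeq2 factors, 140 with total counts and 132 with RPKM values. No ratio whose counting interval left out 1 changed sign, and sign changes of the others were not counted. The depth of the mature pellicle library limits genes with few reads, whose floor is 1.31 counts per 1e+06 scaled reads.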

Other observations

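The genes in this part, and the test of neighbouring genes, were chosen after their values were seen. The aerobic respiratory chain list went both ways, with 9 of 23 members higher and 5 lower in the initial and 8 and 6 in the mature pellicle, and medians within the random ranges. Cytochrome d ubiquinol oxidase, a terminal oxidase with high affinity for oxygen, had log2 ratios against planktonic cells of 3.37 (3.27 to 3.47) for subunit I (BG00_RS08795) and 3.61 (3.48 to 3.75) for subunit 2 (BG00_RS08790) in the initial pellicle, and 2.28 (2.18 to 2.39) and 2.55 (2.40 to 2.70) in the mature pellicle. A cytochrome oxidase subunit I (BG00_RS03400) was at 4.37 (3.76 to 5.05) and 3.95 (3.32 to 4.65). The 6 genes of the cytochrome o oxidase stretch, which include a hypothetical protein, had ratios from -5.17 to -2.42 in the initial and from -5.08 to -3.06 in the mature pellicle. Methylcitrate synthase (BG00_RS12440) and 2-methylisocitrate lyase (BG00_RS12445), enzymes of propionate use, were at 5.04 (4.83 to 5.27) and 4.35 (4.06 to 4.66) in the initial pellicle. In the mature pellicle they were at 4.13 (3.91 to 4.36) and 4.27 (3.97 to 4.58). Glycogen branching protein (BG00_RS16440) and maltodextrin phosphorylase (BG00_RS16450) were at 2.32 (2.04 to 2.61) and 2.84 (2.59 to 3.09) in the initial and 2.99 (2.72 to 3.27) and 2.87 (2.61 to 3.13) in the mature pellicle.

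The 7 genes of the fimbrial stretch BG00_RS08330 to BG00_RS08360 had log2 ratios from 0.16 to 5.51 in the initial and from 1.99 to 10.42 in the mature pellicle. Besides the usher it holds a gene whose KEGG text names a fimbrial chaperone (BG00_RS08340), at 3.04 (2.37 to 3.77) in the initial and 6.72 (6.12 to 7.40) in the mature pellicle against planktonic cells, and a regulator whose KEGG text names the LuxR-family regulator of curli genes (BG00_RS08360), at 0.91 (0.65 to 1.17) and 1.99 (1.76 to 2.23). The chaperonin GroEL (BG00_RS02700) was at 2.89 (2.85 to 2.92) in the initial and 1.77 (1.73 to 1.81) in the mature pellicle.

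Some large ratios fell in stretches of consecutive locus tags. Runs of at least 4 tags that were all at least 4-fold higher held 68 of 256 such genes in the initial pellicle and 69 of 293 in the mature pellicle, and runs of lower genes held 10 of 54 and 10 of 96. In the test of neighbouring genes, log2 ratios of neighbouring tags correlated at 0.447 over 2634 pairs in the initial pellicle. The highest of 1000 shuffles of the gene order reached 0.0652. These pairs include the runs, whose genes all had counting intervals that left out 1. The test therefore gives no separate evidence on counting noise gene by gene as a source of the runs. Variation between cultures of a state cannot be told apart from the pellicle stages, because there is 1 library per state. Reads that span the ends of adjacent genes were not tested as an explanation.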
